A study of Mus musculus with 12 samples.

How the data were processed

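RNA was measured in whole jejunum of 12 C57BL/6 mice, 3 in each of 4 groups. Per the labels' protocols, the tissue was homogenized, RNA was prepared with a DNase digest, and libraries were made with an Illumina TruSeq RNA kit and sequenced as strand-specific read pairs on a HiSeq instrument. The mice came from a cross of a Villin-Cre line, in which Cre recombinase is made in the intestinal epithelium, with a line that carries a floxed Msh2 allele. The wild type mice of the labels carried 2 floxed alleles and no Cre, the null mice 2 floxed alleles and Cre, and the heterozygous mice 1 floxed allele and Cre. The irradiated wild type mice received 0.5 Gy of X-rays and were killed 28 days later, and all mice are listed as 4 months old.

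The authors deposited 1 table of RPKM values (read counts scaled by transcript length and library size), with 1 column per mouse and 1 transcript per gene symbol, per the file headers. The genome build is mm9 per the submitters' processing notes. The aligner, the counting tool, the treatment of reads that map to several places and the use of strand in counting are not given in the sources used here. The rows used here lie on autosomes, so the sex of the animals was not examined and a planned covariate for Y-linked transcripts had no values to work on. Some widely expressed genes, such as Ldha, Hmgcr and Dnmt1, are listed at 0 in all 12 samples, and Gapdh has a mean of 0.194 RPKM. Among transcripts with no base free of other annotated transcripts 32.4% were at 0 in all samples, against 9.9% of those with 50% to under 100% of their bases free and 17.3% of those with no overlapping transcript, so overlap does not account for all zeros. A value of 0 therefore states only how the gene is listed. Genes with near-identical copies, such as the Cyp3a, Defa, lysozyme and H2 families, and genes that overlap others are uncertain, since reads could be split between copies.

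Low values rose in fixed steps within a sample, as whole reads divided by a transcript length would. From the steps, library sizes of 42970401 to 62030559 reads were computed, a ratio of 1.44. With these sizes all 7154 tested genes gave whole reads in all 12 samples within a tolerance of 0.02 reads. In simulated tables the recovery returned the true reads for 99.7% of 908 genes. In a transcript of 2 kb, 1 read was worth 0.0081 to 0.0116 RPKM. The 10 genes with the highest RPKM took 22.1% to 25.7% of each sample's RPKM sum. Pairs of samples of a group differed by far more than counting noise, with a chi-square of 81.9 to 204.4 per gene, so no library was counted as a repeat of another. The labels number the animals separately, and each was taken as 1 replicate.

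Values were tested with limma 3.58.1 in R 4.3.3 on log2(RPKM + 0.5), so fold changes are on that scale and understate the change of low genes. Genes with a mean RPKM of at least 0.5 over the 12 samples were tested. All 4 groups entered 1 fit with 8 residual degrees of freedom, an intensity trend in the empirical Bayes step and no covariate. Tests were two-sided and p-values were adjusted by the Benjamini-Hochberg method, with a threshold of 0.05. No scaling was added to the RPKM. The contrasts were irradiated against unirradiated wild type, null against wild type, heterozygous against wild type, and null against heterozygous. Before the data were examined, 40 lists of cell type markers and pathway genes were fixed, and the 36 lists with at least 4 tested genes were tested with camera at its preset correlation between genes of 0.01, with adjustment over the lists of a comparison. A list score is the mean over its tested genes of the log2 value minus the gene's mean over the 12 samples. The correlation of the radiation and null fold changes was compared with 100 simulations of unchanged groups that share their controls and have 1 spread per gene.

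The genes named in the text follow a rule fixed before the data were examined. The rule takes called genes with groups that do not overlap and a mean of at least 1 RPKM in the higher group, excluding placeholder symbols, as the 8 largest rises and 8 largest falls. It also takes up to 3 called members of each list, or the 2 members with the smallest p of a list that passed with none called, until 30 genes were reached. Where fewer than 5 genes passed, the 5 with the smallest p are given as values. Msh2, Msh6, Mlh1, Lgr5, Olfm4, Mki67, Cdkn1a, Dnmt1 and Setdb1 are given in every comparison, but Mlh1 and Dnmt1 are listed at 0 in all samples, Setdb1 does not exceed 0.00433 RPKM and Olfm4 is not in the table.

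The procedure was tested on simulated values with the real means, spreads and groups, in which 67 genes were changed by 1.5-fold, 67 by 2-fold and 66 by 4-fold in the null group of 7154 genes. For the contrast of null against wild type it called 68.7% of genes changed by 1.5-fold, 94.0% of genes changed by 2-fold and 100.0% of genes changed by 4-fold, and 6 of the 181 genes called were unchanged. Simulated genes varied independently, which real genes do not. The alternatives were pseudocounts of 0.1 and 1, no filter, a mean RPKM of at least 1, median-of-ratios scaling, quantile normalization, robust empirical Bayes, a fit of only the compared groups, each replicate left out in turn, and for lists an estimated correlation and the fry test of limma. Added after seeing the data were limma's voom on the recovered reads and a fit without the 3 libraries rich in B cell transcripts, whose B and plasma cell score was more than 1 log2 unit above the mean. Count models planned for whole reads were not run, although whole reads were recovered, because the deposited unit is RPKM, and voom was run on those reads in their place. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 was used for reading, read recovery and figures.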

Results

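The expression of 7154 autosomal genes was compared in whole jejunum of 12 mice, in 4 groups of 3. The groups were unirradiated Msh2 wild type, wild type 28 days after 0.5 Gy of X-rays, Msh2 heterozygous and Msh2 null. Msh2 encodes a protein of DNA mismatch repair, and the Cre that removes the floxed part of the gene is made in villin-expressing epithelium. Radiation and loss of mismatch repair are the stresses that the series sets side by side. Library sizes, computed from the steps of the deposited RPKM values, were 42970401 to 54361602 reads in wild type, 48751804 to 57126124 in irradiated wild type, 54323382 to 62030559 in heterozygous and 47150577 to 56001174 in null samples. At this depth 1 read in a 2 kb transcript was worth at most 0.0116 RPKM.

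The targeted gene, Msh2 (ENSMUSG00000024151, mm9 chromosome 17, 88071670 to 88123053), was not lower in null than in wild type samples. Its mean was 18.6 ± 0.414 RPKM in wild type, 17.7 ± 3.31 in irradiated wild type, 16.2 ± 1.48 in heterozygous and 20.2 ± 1.23 in null samples (SD, n = 3 each). In single samples it was 18.7, 18.9 and 18.1 RPKM in wild type and 19.5, 21.7 and 19.5 RPKM in null. The log2 fold change of null against wild type was 0.12 (95% interval -0.15 to 0.38; limma, unadjusted p = 0.344), and that of heterozygous against wild type was -0.20 (-0.46 to 0.07; limma, unadjusted p = 0.129). Null samples were above heterozygous samples by 0.32, with a 95% interval that was positive throughout (0.05 to 0.58). This difference did not pass over all genes (limma adjusted p = 0.995). That p is adjusted over all genes, so it cannot be set beside the unadjusted p of the other contrasts. The Msh2 value covers a whole transcript in tissue that also holds cells without Cre. It therefore does not check which samples lost the floxed segment.

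**Figure D1:**
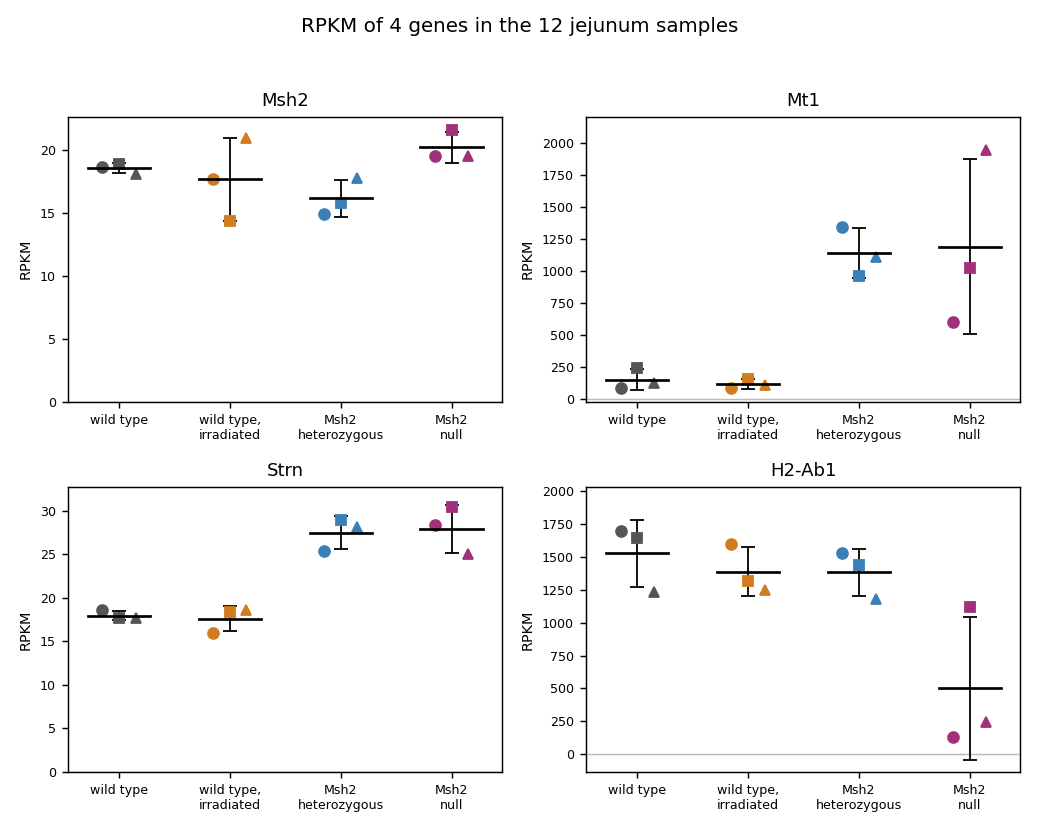
RPKM (linear axes) of Msh2, Mt1, Strn and H2-Ab1 in the 12 samples, grouped by genotype and treatment, where symbols are single mice (circle, square and triangle for replicates 1, 2 and 3), horizontal lines are group means and error bars are SD. Msh2 lies between 14.3 and 21.7 RPKM throughout, Mt1 and Strn are higher in every heterozygous and null sample than in every wild type sample, and H2-Ab1 is 130 and 244 RPKM in 2 of the 3 null samples.

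Radiation. The irradiated and unirradiated wild type jejunum differed in no single gene past the threshold 28 days after 0.5 Gy. The 5 genes with the smallest p were all lower in the irradiated group. Tnc, which encodes the matrix protein tenascin C, was 3.51 ± 0.0970 RPKM against 5.45 ± 0.707, Cyr61, a matricellular protein gene, was 1.51 ± 0.395 against 2.58 ± 0.352, and Sgk1, a kinase induced by steroids, was 6.41 ± 2.07 against 11.4 ± 2.48 (SD, n = 3). Serpinb1c was 10.5 RPKM against 14.3 and Ttc30a1 was 0.909 RPKM against 1.42. The adjusted p of each of the 5 was 1 (limma). Of the 7154 genes, 0 passed with limma and 0 with voom, and 139 had an unadjusted p under 0.05 with either, which is 1.9% of the genes. The groups did not overlap in 5.6% of genes, where chance gives 10%.

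Of 36 lists, 4 passed camera at its preset correlation in the radiation comparison. Unfolded protein response genes were lower (13 of 16 members, median log2 fold change -0.24, adjusted p = 3.32e-05; adjusted p = 0.87 with an estimated correlation), among them the endoplasmic reticulum chaperone genes Pdia4, at 90.2 RPKM against 114, and Sdf2l1, at 46.3 against 65.6. Macrophage and dendritic cell markers were lower in 10 of 10 members (median -0.37, adjusted p = 0.00907; adjusted p = 0.87 with an estimated correlation). Csf1r, the receptor of a macrophage growth factor, was 6.41 RPKM against 9.58, and the chemokine receptor gene Cx3cr1 was 0.869 against 1.46. Mesenteric fat markers were higher in 5 of 5 members (median 1.41, adjusted p = 0.0433; adjusted p = 0.87 with an estimated correlation), with Fabp4 at 85.7 ± 47.7 RPKM against 31.3 ± 21.1 and Adipoq at 19.6 ± 11.1 against 7.10 ± 4.09. Paneth cell markers were lower in 12 of 13 members (median -0.18, adjusted p = 0.0433; adjusted p = 0.87 with an estimated correlation), with the defensin genes Defa3 at 218 RPKM against 280 and Defa24 at 513 against 636. No member of any list passed over all genes, and 0 passed when adjusted over the list alone. Every one of the 4 calls ended with some library left out. The adjusted p was 0.052 for the unfolded protein response without wild type replicate 1, 0.365 for macrophages without wild type replicate 2 and 0.121 without irradiated replicate 2. It was 0.371, 0.131 and 0.163 for fat without wild type replicate 2, irradiated replicate 2 and irradiated replicate 3. For Paneth cells it was 0.373, 0.0842, 0.339 and 0.403 without wild type replicates 1 and 3 and irradiated replicates 2 and 3. Calls also ended under other settings. With a pseudocount of 0.1 the adjusted p was 0.0645 for fat and 0.0564 for Paneth cells, with median-of-ratios scaling 0.0833 and 0.065, and with quantile normalization 0.075 and 0.0761. It was 0.0558 for fat with voom and 0.11 for Paneth cells with no filter on low values. Without the 3 libraries rich in B cell transcripts it was 0.611 for fat, 0.134 for Paneth cells and 0.108 for macrophages.

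The lists nearest to the question of radiation stress did not pass. Targets of p53 had a median log2 fold change of 0.05 over 17 genes (camera adjusted p = 0.15), histone methyltransferases and demethylases 0.07 over 18 genes (adjusted p = 0.154), genes of the DNA methylation machinery -0.11 over 7 genes (adjusted p = 0.185) and crypt stem cell markers 0.01 over 11 genes (adjusted p = 0.936, with a mean of -0.00 and a test direction of lower). Cdkn1a, the p53 target that encodes p21, was 3.03 ± 0.402 RPKM after radiation and 3.22 ± 0.347 without, and its log2 fold change of -0.07 became 0.01 without irradiated replicate 3 and 0.07 without the 3 libraries rich in B cell transcripts. Lgr5, the marker of crypt base stem cells, was 5.67 ± 0.185 against 6.21 ± 0.466, and Mki67, a marker of dividing cells, was 44.0 ± 1.70 against 45.6 ± 1.24 (SD, n = 3). Msh6, which encodes the partner of Msh2, had a log2 fold change of 0.07 (95% interval -0.11 to 0.24). The number of lists that passed depended on single samples, since 2 lists passed without irradiated replicate 2, 7 without irradiated replicate 3 or without wild type replicate 1, and 10 without irradiated replicate 1. Without the 3 libraries rich in B cell transcripts 1 list passed.

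Msh2 loss. Null jejunum had more RNA of cholesterol synthesis and xenobiotic genes and less of interferon-gamma, T cell and macrophage genes than wild type jejunum. This held by list and only at the preset correlation of camera (adjusted p = 0.42 to 0.57 with an estimated correlation). No single gene passed the threshold over all genes. Mt1, which encodes the metal-binding protein metallothionein 1 (ENSMUSG00000031765, chromosome 8, 96702989 to 96704225), was 1190 ± 689 RPKM in null and 149 ± 79.8 RPKM in wild type samples, a ratio of 7.98. Rtn4r, the Nogo receptor gene (ENSMUSG00000043811, chromosome 16, 18127735 to 18152501), was 3.28 ± 0.308 against 1.51 ± 0.107 RPKM. The alkaline ceramidase gene Acer1 (ENSMUSG00000045019, chromosome 17, 57092913 to 57121549) was 22.1 ± 3.41 against 10.6 ± 1.61, and Strn, the gene of the scaffold protein striatin (ENSMUSG00000024077, chromosome 17, 79053936 to 79088157), was 28.0 ± 2.75 against 18.0 ± 0.514 (SD, n = 3). Each of these 4 had a limma adjusted p of 0.0543, with log2 fold changes of 2.96 ± 0.43, 0.91 ± 0.12, 1.02 ± 0.15 and 0.62 ± 0.09 (± SE). AI597468 (chromosome 10, 84565372 to 84580492) was lower, at 10.3 RPKM against 16.0, with an adjusted p of 0.09.

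Cholesterol synthesis genes were higher in null samples in 16 of 16 members, with a median log2 fold change of 0.59 (camera adjusted p = 6.36e-13; adjusted p = 0.42 with an estimated correlation). When adjusted over the list alone 14 of the 16 passed with limma, and 0 over all genes. Cyp51, which encodes lanosterol demethylase, was 115 ± 41.4 RPKM in null and 59.5 ± 5.73 in wild type, and the sterol reductase gene Tm7sf2 was 71.4 ± 18.8 against 46.1 ± 3.76 (SD, n = 3). Xenobiotic and glutathione genes were higher in 20 of 24 members (median 0.31, adjusted p = 0.000241; adjusted p = 0.57 with an estimated correlation), with the glutathione transferase gene Gstp1 at 82.1 RPKM against 67.8 and the cytochrome gene Cyp2c66 at 26.5 against 11.2. Fatty acid oxidation genes were higher in 13 of 15 members (median 0.23, adjusted p = 0.00983; adjusted p = 0.77 with an estimated correlation), with the thiolase gene Acaa1b at 41.7 RPKM against 24.1 and Ehhadh at 73.0 against 63.6. No xenobiotic or fatty acid oxidation gene passed when adjusted over the list alone. The fatty acid oxidation call ended without wild type replicate 2 (adjusted p = 0.051), without null replicate 3 (adjusted p = 0.0701) and without the 3 libraries rich in B cell transcripts (adjusted p = 0.178). Mesenteric fat markers were higher in null samples as well, in 5 of 5 members (median 1.53, camera adjusted p = 0.132). Over the 12 samples the fat and fatty acid oxidation scores had a correlation of 0.63, and of 0.62 with group means removed, so a change in the oxidation genes was not separated from fat in the tissue.

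The MHC class I and interferon-gamma list was lower in null samples in 14 of 14 members (median -0.47, camera adjusted p = 1.42e-09; adjusted p = 0.42 with an estimated correlation), and 10 members passed when adjusted over the list alone. Psmb8, a subunit of the immunoproteasome, was 99.2 ± 43.0 RPKM against 190 ± 37.8, and H2-D1, a class I molecule, was 258 ± 33.9 against 358 ± 54.8 (SD, n = 3). MHC class II genes were lower in 9 of 10 members (median -1.61, adjusted p = 0.0002; adjusted p = 0.42 with an estimated correlation), of which 5 passed when adjusted over the list alone. H2-Ab1 (ENSMUSG00000073421, chromosome 17, 34400185 to 34406355) was 130, 1123 and 244 RPKM in the null samples against 1700, 1646 and 1235 in wild type, and Cd74, the invariant chain gene, was 4.60, 36.3 and 10.6 against 51.2, 48.1 and 39.99. Markers of T cells and intraepithelial lymphocytes were lower in 13 of 14 members (median -0.99, adjusted p = 1.06e-06; adjusted p = 0.42 with an estimated correlation), with 0 passing when adjusted over the list alone. The T cell receptor component gene Cd3e was 1.47, 4.70 and 1.43 RPKM in null against 5.72, 5.45 and 3.56 in wild type, and Nkg7, a gene of cytotoxic granules, was 3.13, 8.90 and 1.89 against 12.9, 8.30 and 7.63. Macrophage and dendritic cell markers were lower in 10 of 10 members (median -0.69, adjusted p = 1.06e-06; adjusted p = 0.42 with an estimated correlation) and 5 passed when adjusted over the list alone. Csf1r was 4.64 ± 0.543 RPKM in null against 9.58 ± 3.19 in wild type, and Cx3cr1 was 0.605 ± 0.0886 against 1.46 ± 0.460 (SD, n = 3). Transcripts of B and plasma cells, of which B cells also carry class II molecules, were high in wild type replicate 2, irradiated replicate 3 and null replicate 3, with list scores of 2.62, 2.41 and 1.84, against at most -0.48 in the other samples.

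The enteroendocrine, Paneth cell, absorptive enterocyte and cell cycle lists also passed camera as lower in null samples. Other epithelial lists did not pass, with medians of 0.01 for goblet cells (adjusted p = 0.798), 0.07 for crypt stem cells (0.754), -0.04 for tuft cells (0.661), 0.06 for duodenum-type (0.534) and 0.38 for ileum-type enterocytes (0.0537). Enteroendocrine markers were lower in 7 of 9 members (median -0.26, camera adjusted p = 0.000383; adjusted p = 0.42 with an estimated correlation), and 5 passed when adjusted over the list alone. The chromogranin genes Chga and Chgb were 25.4 ± 4.14 and 22.2 ± 2.34 RPKM in null against 42.3 ± 9.54 and 32.2 ± 6.95 in wild type (SD, n = 3). Cell cycle genes were lower in 16 of 16 members by a small amount (median -0.16, adjusted p = 5.19e-05; adjusted p = 0.57 with an estimated correlation). Ccnb1, the cyclin B1 gene, was 5.83 RPKM against 8.20, and the kinetochore motor gene Cenpe was 7.96 against 9.70. Paneth cell markers were lower in 13 of 13 members (median -0.28, adjusted p = 0.00514; adjusted p = 0.77 with an estimated correlation), with the Paneth lysozyme gene Lyz1 at 6014 RPKM against 9496 and Defa-rs1 at 1137 against 1409. Absorptive enterocyte markers were lower in 13 of 17 members (median -0.18, adjusted p = 0.00983; adjusted p = 0.57 with an estimated correlation). Apoa4, an apolipoprotein gene, was 1306 ± 670 RPKM against 3275 ± 663, and Rbp2, a retinol carrier gene, was 564 ± 120 against 722 ± 76.6 (SD, n = 3). No cell cycle, Paneth cell or enterocyte gene passed when adjusted over the list alone. Without null replicate 3 the adjusted p was 0.301 for Paneth cells and 0.425 for enterocytes, and it was 0.0826 for Paneth cells without wild type replicate 1 and 0.221 for enterocytes without wild type replicate 3. Without the 3 libraries rich in B cell transcripts it was 0.0813 and 0.0596, and with no filter on low values it was 0.175 for enterocytes.

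Crypt stem cell markers, p53 targets, mismatch repair genes and histone methyltransferases and demethylases did not pass in null against wild type, with camera adjusted p of 0.754, 0.0619, 0.0965 and 0.645. Lgr5 was 4.71 ± 0.198 RPKM in null and 6.21 ± 0.466 in wild type (SD, n = 3), with a limma adjusted p of 0.323. Mki67 had a log2 fold change of -0.18 (95% interval -0.36 to 0.00). Cdkn1a had a log2 fold change of -0.03 (-0.41 to 0.35) and Msh6 one of 0.02 (-0.16 to 0.19), both of which took the other sign under quantile normalization, and Msh6 under median-of-ratios scaling as well. Across all genes 0 passed with limma and 0 with voom, 734 (10.3%) and 699 had an unadjusted p under 0.05, and the groups did not overlap in 1214 genes, where chance gives 10% of the 7154. With median-of-ratios scaling 4 genes passed, which were Acer1, Mt1, Rtn4r and Tnc. Without null replicate 2, whose class II and T cell values lay nearest to wild type, 23 genes passed, among them H2-Ab1, Cd74, Cd3e, Nkg7, Psmb8, Cyp51, Mt1 and Rtn4r.

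**Figure D2:**
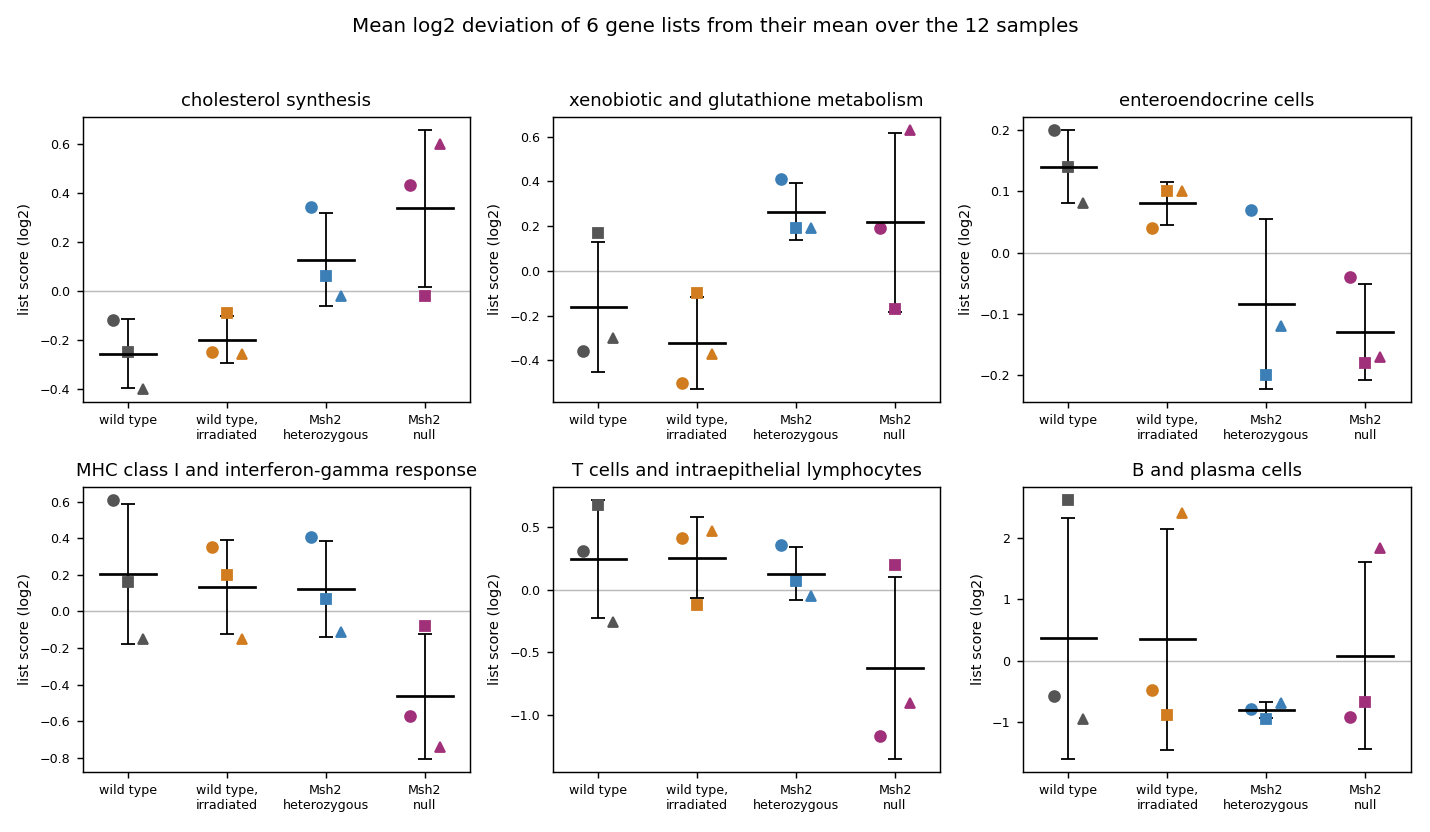
List scores (log2 units, mean deviation of the tested members from their mean over the 12 samples) of 6 gene lists in the 4 groups, where symbols are single mice (circle, square and triangle for replicates 1, 2 and 3), horizontal lines are group means and error bars are SD. Cholesterol synthesis scores are at least -0.02 in heterozygous and null samples and at most -0.09 in both wild type groups, null replicates 1 and 3 have the lowest T cell scores, and B cell scores stand out in 3 samples of 3 groups.

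Loss of 1 Msh2 allele. The heterozygous jejunum had higher metallothionein, striatin, cholesterol and xenobiotic values than the wild type samples that the null jejunum was compared with, again with no gene past the threshold over all genes. The common controls make the heterozygous and null changes alike even without any change. Unchanged heterozygous and null groups simulated against shared controls gave a correlation of 0.502 ± 0.027 across genes (SD, 100 simulations). The observed correlation was 0.605. The simulation gave all groups 1 spread per gene. Real wild type pairs differed less (chi-square 81.9 to 93.4 per gene) than heterozygous and null pairs (107.4 to 204.4). This chi-square is of reads and does not measure the spread of log2 values. How much of the likeness comes from the controls was therefore not measured. The cholesterol and xenobiotic lists passed only at the preset correlation (adjusted p = 0.42 and 0.52 with an estimated correlation). Mt1 was 1139 ± 193 RPKM against 149 ± 79.8 (log2 fold change 3.05 ± 0.43 SE; limma adjusted p = 0.119). Strn was 27.5 ± 1.89 RPKM against 18.0 ± 0.514 (0.60 ± 0.09 SE; limma adjusted p = 0.152). Tnc was lower, at 3.33 RPKM against 5.45, and the steroid-metabolizing cytochrome genes Cyp3a57 and Cyp3a41a were higher, at 3.34 against 1.80 and 6.64 against 2.45 RPKM, each with a limma adjusted p of 0.681. The wild type values of Mt1 were 85.2, 238 and 124 RPKM, and Mt1 passed (adjusted p = 0.0444) when wild type replicate 2, the highest, was left out.

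By list, 6 of 36 passed camera at the preset correlation in heterozygous against wild type jejunum. Cholesterol synthesis genes were higher in 16 of 16 members (median 0.40, adjusted p = 6.42e-13; adjusted p = 0.42 with an estimated correlation), with the reductase gene Dhcr7 at 30.8 ± 3.17 RPKM against 25.6 ± 0.574 and the sterol oxidase gene Sc4mol at 142 ± 32.4 against 89.7 ± 19.2 (SD, n = 3). Xenobiotic and glutathione genes were higher in 21 of 24 members (median 0.25, adjusted p = 5.03e-10; adjusted p = 0.52 with an estimated correlation). Cyp3a11 was 1036 ± 194 RPKM against 385 ± 144, the carboxylesterase gene Ces2a was 77.4 ± 5.60 against 38.0 ± 11.5 (SD, n = 3), and 3 members passed when adjusted over the list alone. Macrophage and dendritic cell markers were lower in 10 of 10 members (median -0.63, adjusted p = 6.78e-06; adjusted p = 0.63 with an estimated correlation), with Csf1r at 5.63 RPKM against 9.58 and Cx3cr1 at 0.751 against 1.46. Enteroendocrine markers were lower in 7 of 9 members (median -0.29, adjusted p = 0.000324; adjusted p = 0.42 with an estimated correlation), with Chgb at 22.4 RPKM against 32.2 and the neurotensin gene Nts at 156 against 190. No gene of the other 3 lists passed when adjusted over the list alone, and the enteroendocrine call ended with no filter on low values (adjusted p = 0.238).

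B and plasma cell markers were lower in heterozygous samples in 9 of 9 members (median -1.18, camera adjusted p = 0.0103; adjusted p = 0.82 with an estimated correlation), beside the high score of wild type replicate 2. Cr2, a complement receptor gene of B cells and follicular dendritic cells, was 0.300, 7.04 and 0.0533 RPKM in wild type and at most 0.104 RPKM in heterozygous samples. Igj, which encodes the immunoglobulin joining chain, was 31.5 ± 9.68 RPKM against 68.7 ± 46.5 (SD, n = 3). The B cell list had an adjusted p of 0.648 without wild type replicate 2, 0.103 without heterozygous replicate 3 and 0.731 without the 3 libraries rich in B cell transcripts. With no filter on low values it was 0.12 and with voom 0.0769. Unfolded protein response genes were lower in 14 of 16 members (median -0.14, adjusted p = 0.0329; adjusted p = 0.82 with an estimated correlation), with Creld2 at 46.5 RPKM against 67.8 and Pdia4 at 98.7 against 114. This call ended without wild type replicate 1 (adjusted p = 0.882), without heterozygous replicate 3 (0.797), with no filter (0.275) and with median-of-ratios scaling (0.0562), and 11 lists passed in all when heterozygous replicate 1 was left out.

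Msh6 was 16.2 ± 1.25 RPKM in heterozygous and 20.0 ± 0.471 RPKM in wild type samples (SD, n = 3), with a limma adjusted p of 0.997 and an unadjusted p of 0.00343. It was the 1 gene of the mismatch repair list that passed when adjusted over the list alone (adjusted p = 0.0446), while the list did not pass (camera adjusted p = 0.3). Lgr5, Mki67 and Cdkn1a had log2 fold changes of -0.23 (95% interval -0.47 to 0.01), -0.05 (-0.24 to 0.13) and 0.09 (-0.29 to 0.47). Across all genes 0 passed with limma and 0 with voom, and 232 (3.2%) and 243 had an unadjusted p under 0.05.

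Loss of the second Msh2 allele. Among the Cre-positive mice, null jejunum had less RNA of interferon-gamma, T cell, class II and cell cycle genes than heterozygous jejunum. This held by list and only at the preset correlation of camera (adjusted p = 0.73 to 0.82 with an estimated correlation). Mt1 and Strn did not separate the groups. The log2 fold change of Mt1 was -0.09 (95% interval -1.03 to 0.85) and that of Strn 0.02 (-0.18 to 0.23). The genes with the smallest p were Oplah, the 5-oxoprolinase gene of glutathione turnover, at 14.7 ± 0.634 RPKM in null against 9.36 ± 1.20 in heterozygous samples, Pipox, a pipecolate oxidase gene, at 13.4 ± 1.05 against 20.5 ± 2.68, and Tlr4, the receptor gene for lipopolysaccharide, at 2.17 ± 0.648 against 0.681 ± 0.246 (SD, n = 3). Rtn4r was 3.28 RPKM against 1.98 and Gm14420 was 4.97 against 2.47. All 5 had a limma adjusted p of 0.625.

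The MHC class I and interferon-gamma list was lower in null than in heterozygous samples in 14 of 14 members (median -0.40, camera adjusted p = 1.32e-11; adjusted p = 0.73 with an estimated correlation), with Psmb8 at 99.2 ± 43.0 RPKM against 179 ± 29.6 and Ido1, which encodes a tryptophan-degrading enzyme, at 3.24 ± 1.13 against 7.58 ± 2.57 (SD, n = 3). T cell and intraepithelial lymphocyte markers were lower in 12 of 14 members (median -1.0, adjusted p = 1.55e-08; adjusted p = 0.73 with an estimated correlation), and 8 passed when adjusted over the list alone. Cd3e was 1.47, 4.70 and 1.43 RPKM against 6.10, 5.97 and 4.89, and Klrd1, a receptor gene of natural killer and cytotoxic cells, was 1.81, 5.35 and 1.59 against 8.96, 7.81 and 4.76. Class II genes were lower in 6 of 10 members (median -1.28, camera adjusted p = 0.000653, and 0.82 with an estimated correlation), and 5 passed when adjusted over the list alone. H2-Ab1 was 499 ± 544 RPKM against 1383 ± 181 and H2-DMb1 52.1 ± 65.6 against 149 ± 32.3 (SD, n = 3). The class II scores were -2.14, -0.16 and -0.24 in null against 0.09, -0.07 and -0.19 in heterozygous samples. By this score only null replicate 1 stood apart. By single genes null replicate 3 was low too. H2-Ab1 was 130, 1123 and 244 RPKM in null against 1529, 1439 and 1180 in heterozygous samples. H2-DMb1 was 10.7, 127.7 and 17.8 against 181.7, 148.7 and 117.2. Null replicate 3 was among the libraries rich in B cell transcripts. The class II call was kept in all 15 other camera fits. B and plasma cell markers, of which B cells carry class II molecules, were higher in null samples in 8 of 9 members (median 0.93, camera adjusted p = 0.246). Cell cycle genes were lower in 15 of 16 members (median -0.14, adjusted p = 0.00011; adjusted p = 0.82 with an estimated correlation), with Plk1 at 12.7 RPKM against 14.7 and Ccnb1 at 5.83 against 7.30. No gene of the interferon-gamma or cell cycle list passed when adjusted over the list alone. The cell cycle call ended without heterozygous replicate 1 (adjusted p = 0.136) and without null replicate 1 (adjusted p = 0.126).

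Further lists passed in null against heterozygous samples with higher adjusted p. Cholesterol synthesis genes were higher in 16 of 16 members (median 0.19, camera adjusted p = 0.0108; adjusted p = 0.82 with an estimated correlation), with Pcsk9 at 26.5 RPKM against 16.3 and Dhcr24 at 203 against 164. Fatty acid oxidation genes were higher in 14 of 15 members (median 0.18, adjusted p = 0.0325; adjusted p = 0.82 with an estimated correlation), with Acaa1b at 41.7 RPKM against 26.5 and the kinase gene Pdk4 at 4.15 against 1.72. Mesenteric fat markers, whose score went with that of fatty acid oxidation, were higher in 5 of 5 members (median 1.18, adjusted p = 0.246). Antimicrobial and inflammatory genes were lower in 10 of 12 members (median -0.11, adjusted p = 0.0325; adjusted p = 0.82 with an estimated correlation), with Pigr, the transporter gene of secreted immunoglobulin, at 947 RPKM against 1119 and the chemokine gene Cxcl9 at 1.16 against 1.99. No gene of the 3 lists passed when adjusted over the list alone. All 3 calls ended without heterozygous replicate 2, without null replicate 1 and without null replicate 3, with adjusted p of 0.06 to 0.273. Cholesterol synthesis also lost its call without heterozygous replicate 3 (adjusted p = 0.357), and the other lists theirs without heterozygous replicate 1 (adjusted p = 0.175 and 0.317). Without the 3 libraries rich in B cell transcripts all 3 ended, with adjusted p of 0.32, 0.231 and 0.233. With no filter the adjusted p was 0.155 for fatty acid oxidation and 0.107 for antimicrobial genes, and for the latter it was 0.114 with median-of-ratios scaling and 0.143 with quantile normalization. Msh2 and Msh6 were both higher in null samples, with log2 fold changes of 0.32 (95% interval 0.05 to 0.58) and 0.31 (0.14 to 0.49) and limma adjusted p of 0.995 and 0.833. Msh6 was the 1 mismatch repair gene that passed when adjusted over the list alone (adjusted p = 0.0302). These groups also differ in carrying 2 floxed alleles or 1. Lgr5, Mki67 and Cdkn1a had log2 fold changes of -0.13 (-0.37 to 0.11), -0.13 (-0.31 to 0.06) and -0.12 (-0.50 to 0.26). Across all genes 0 passed with limma and 0 with voom, and 317 (4.4%) and 327 had an unadjusted p under 0.05. Without null replicate 2, 14 genes passed, among them H2-Ab1, H2-DMb1, Cd74 and Cd3e, and without heterozygous replicate 3, 13 lists passed.

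Shared change of radiation and Msh2 loss. The fold changes of irradiated and of null jejunum against the same wild type samples had a correlation of 0.333 across the 7154 genes, which are not independent replicates. Unchanged groups simulated against shared controls gave a correlation of 0.497 ± 0.030 (SD, 100 simulations). The covariance was 0.0143, against 0.0199 ± 0.0017 in the simulations. The 2 changes had the same sign in 61.8% of genes, against 66.6% in the simulations. The simulations gave all groups 1 spread per gene. Real wild type pairs differed less (chi-square 81.9 to 93.4 per gene) than irradiated (116.5 to 182.4) and null pairs (109.2 to 204.4). This chi-square is of reads and does not measure the spread of log2 values. Controls with a smaller log2 spread would lower the simulated values, so the observed shortfall below them is not read as a result. No gene passed in both comparisons. At an unadjusted p under 0.05 in both there were 48 genes, of which 48 had the same sign. Unchanged groups simulated against shared controls gave 80.1 such genes on average, but from lists of other sizes, 351.6 genes for radiation and 353.0 for Msh2 loss against the real 139 and 734, so the 2 overlaps cannot be ranked. Both comparisons use the same 3 control samples, which are too few to be split. With 1 control left out the correlation was 0.387 without replicate 1, 0.414 without replicate 2 and 0.567 without replicate 3. Simulated unchanged groups with 2 controls gave 0.597, again with 1 spread for all groups.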

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

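The fits with voom and without the 3 libraries rich in B cell transcripts were chosen after the data were seen. The count of genes was 0 under every planned and added setting for radiation. For null against wild type it was 1 with no filter (Slfn4), 4 at a mean RPKM of at least 1 (Acer1, Mt1, Rtn4r and Strn), 4 with median-of-ratios scaling and 5 with quantile normalization (Acer1, Mt1, Rtn4r, Tlr4 and Tnc), where the smallest adjusted p moved from 0.0543 to 0.0318. In other settings the smallest adjusted p rose, to 0.311 in a fit of only the 2 groups, 0.168 without wild type replicate 1, 0.146 without wild type replicate 3 and 0.141 without null replicate 3, and Strn had 0.143 with median-of-ratios scaling. With 1 replicate left out the count was 0 to 23, and the 23 came without null replicate 2. For heterozygous against wild type it was 1 without the libraries rich in B cell transcripts and 0 to 1 with 1 replicate left out, where the gene was Mt1 without wild type replicate 2. For null against heterozygous it was 0 to 14 with 1 replicate left out, and the 14 came without null replicate 2. The number of lists was more sensitive. With an estimated correlation or with fry's directional test it was 0 in all 4 comparisons (fry's mixed test called 1, enteroendocrine cells in Msh2 loss, adjusted p = 0.039), so each list call rests on the preset correlation; estimated correlations of called lists were as high as 0.98, in mesenteric fat. From 4 lists for radiation it moved to 2 with a pseudocount of 0.1, to 1 without the libraries rich in B cell transcripts, and to between 2 and 10 with 1 replicate left out. From 11 lists for Msh2 loss it moved to between 10 and 15 with 1 replicate left out. From 6 lists for loss of 1 allele it moved to 3 with no filter and to between 7 and 11 with 1 replicate left out. From 7 lists for loss of the second allele it moved to between 5 and 13 with 1 replicate left out. The correlation of the radiation and null changes was between 0.387 and 0.567 with a control sample left out. Simulated unchanged groups with 2 controls and 1 spread for all groups gave 0.597. The cause of the other moves was not tested. The Msh2 difference of null against wild type kept its sign and stayed short of the threshold in all settings run, at 0.07 to 0.16, and so did that of heterozygous against wild type, at -0.27 to -0.14.

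Of 1533 values of named genes under the alternatives, 1497 kept their direction and their side of the threshold, 24 passed the threshold, 12 changed sign without passing it, and 0 reversed while called. The 12 were values of Msh2, Msh6 and Cdkn1a, none beyond 0.17. The lists that kept both call and direction in all 15 other camera fits for Msh2 loss were the cholesterol synthesis, MHC class I and interferon-gamma, macrophages, T cells, cell cycle, class II, xenobiotic and enteroendocrine lists. No scaling moved the median fold change of all genes by more than 0.1. Keeping every row as its own feature equals the reported fit, because the table has 1 row per symbol. The Y-linked covariate had no rows to work on, and the planned count models for whole reads were not run, because the deposited unit is RPKM, although the reads were recovered. No paired analysis was possible because the groups share no animal, litter or batch number in the labels. Depth limits low genes, since 1 read in a 2 kb transcript is worth 0.0081 to 0.0116 RPKM, but genes tested here averaged at least 0.5 RPKM.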

Other observations

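The comparison of Cre-positive with Cre-negative mice was chosen after the results were seen. So was every test in this part except the counts of other splits and the planned test of the ileum-type list. The 6 Cre-positive mice (heterozygous and null) differed from the 6 Cre-negative mice (wild type, irradiated or not) in 4 of 7154 genes by limma at an adjusted p under 0.05, and 678 had an unadjusted p under 0.05. Mt1 was 1160 ± 453 RPKM against 131 ± 58.6 (SD, n = 6), a ratio of 8.86, with ranges of 601 to 1950 and 84.7 to 238 RPKM. Strn was 27.7 ± 2.13 against 17.8 ± 1.0, Acer1 19.7 ± 3.45 against 10.6 ± 1.60, and AI597468 11 ± 1.31 against 15.8 ± 0.877 RPKM. Their limma adjusted p were 0.00033, 0.000356, 0.013 and 0.0205, and in each the 6 values of one side lay apart from the 6 of the other. Voom called 4 genes, the same 4; median-of-ratios scaling and quantile normalization called 4 genes each, 3 of them the same; and with 1 library left out 2 to 9 genes passed. The 9 came without wild type replicate 2 and again without null replicate 2, and held the first 4 genes, and the 2 came without wild type replicate 1. The next 5 genes by p did not pass. Cyp3a44 was 3.07 times as high in Cre-positive mice, Ces2a 2.28 times, Nlrc4 1.45 times, Cyp3a41a 2.53 times and Cyp3a11 2.52 times, with adjusted p of 0.0531, 0.0928 and, for the last 3, 0.102. The Cyp3a genes are near-identical copies, and how reads were assigned among them is not given. Of 36 lists 14 passed camera at the preset correlation and 0 with an estimated correlation. Xenobiotic genes were higher in 23 of 24 members (camera adjusted p = 1.28e-10; adjusted p = 0.28 with an estimated correlation, 0.075 with fry), and enteroendocrine markers were lower in 6 of 9 (camera adjusted p = 6.25e-05; adjusted p = 0.19 with an estimated correlation, 0.038 with fry). Macrophage markers were lower in 10 of 10 members (median -0.50, adjusted p = 9.54e-06; adjusted p = 0.59 with an estimated correlation). The MHC class I and interferon-gamma list was lower in 13 of 14 (median -0.20, adjusted p = 0.000284; adjusted p = 0.73 with an estimated correlation). T cell markers were lower in 13 of 14 (median -0.56, adjusted p = 0.000531; adjusted p = 0.65 with an estimated correlation) and class II genes in 9 of 10 (median -0.97, adjusted p = 0.00314; adjusted p = 0.59 with an estimated correlation). The enterocyte, cell cycle, type I interferon, B cell and Paneth cell lists were lower and the fatty acid oxidation and ileum-type lists higher, with adjusted p of 0.00325 to 0.0481 (adjusted p = 0.59 to 0.73 with an estimated correlation).

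Tissue composition differed between mice within groups. The mesenteric fat score was -4.17 in heterozygous replicate 2 and 2.54 in heterozygous replicate 3. The clock output gene Dbp ranged from 0.327 to 22.6 RPKM over the 12 samples. Ileum-type enterocyte markers were higher in null than in wild type samples in 5 of 5 members, with a median log2 fold change of 0.38 and a camera adjusted p of 0.0537.

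Genes that separate Cre-positive from Cre-negative mice. Of 100 splits of the 12 samples into 6 and 6, drawn from 462 and including the real one, 3 gave at least 4 genes and the highest other split gave 6. The Cre division was chosen after the results were seen, so its place among the splits does not test chance. Loss of both Msh2 alleles is argued against as the whole source. The 5 genes with the smallest p of null against unirradiated wild type were tested in heterozygous against irradiated wild type. In a fit of those 6 libraries alone, 4 of the 5 differed on the same side (limma, Holm adjusted p of 3.18e-06 to 0.0177, Mt1 2.83 to 3.87). These are the 4 genes of the Cre comparison. The rank of the 5 rests on null and unirradiated wild type means, but on a spread taken from all 12 samples. The choice of genes is therefore not fully independent of the tested samples. The Cre comparison drew on the means of the tested samples as well. Rtn4r, outside the pattern, did not differ (0.11, -0.23 to 0.45) as loss of both alleles predicts. For Acer1 and AI597468 a further effect of the second allele stays open, since null minus heterozygous was 0.33 (-0.00 to 0.67) and -0.19 (-0.40 to 0.03). Further, a haplotype that every floxed allele carries is argued against for Strn and Acer1. Null and wild type mice are both homozygous for the floxed allele, and Strn still differed by 0.62 (0.42 to 0.82). The labels give the genotype at Msh2 only (88071670 to 88123053). Floxed chromosomes that differ at Strn (79053936 to 79088157) or Acer1 (57092913 to 57121549) stay open. The labels trace the Villin-Cre line to a B6.SJL strain. A haplotype on chromosome 17 that travels with the transgene may therefore account for Strn and Acer1, which stays open. Without the 4 called genes, 3 of 19 genes with p under 0.001 lie on that chromosome where 1.0 was expected (Fisher's exact test, p = 0.078). At p under 0.01, 10 of 157 lie there where 8.4 were expected (Fisher's exact test, p = 0.59). The 3 genes are Nlrc4, higher in Cre-positive mice, and Xdh and Ppm1b, lower in them. They lie between 74233248 and 85423331, as Strn does and Acer1 does not. The test covers the whole chromosome, and whether these genes cluster was not tested. Such a haplotype cannot act in cis on Mt1 and AI597468, of which 0 lie on chromosome 17. Cre and the loss of 1 allele cannot be told apart because no group carries Cre with both Msh2 alleles intact, nor can a difference in litter, cage or day, because 0 Cre-negative mice are numbered within the range of the Cre-positive mice.

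Lower interferon-gamma list in null jejunum. The score of the MHC class I and interferon-gamma list was 0.67 log2 units lower in null than in wild type samples (difference -0.67, 95% interval -1.27 to -0.08). With the macrophage and dendritic cell score as a covariate the difference did not shrink, at -0.89 (-1.66 to -0.11). This does not settle whether fewer macrophages contribute. Within the wild type, irradiated and null groups that score was highest in the library rich in B cell transcripts (0.85, 0.45 and -0.00). With the T cell and intraepithelial lymphocyte score as a covariate the difference was -0.34 (-1.01 to 0.34). Fewer T cells may account for part of it, and which of the lists leads was not tested. Most abundant among the tested markers were Gzma, at 150 ± 57.2 RPKM in wild type and 68.3 ± 69.6 in null, and Lyz2, at 427 ± 67.2 and 277 ± 28.7 (SD, n = 3). Whole jejunum normally holds these cells, and 0 of the 14 T cell and 0 of the 10 macrophage markers are in another list.

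Higher cholesterol synthesis in Cre-positive mice. The list score was 0.46 higher in Cre-positive mice (95% interval 0.20 to 0.72), and 6 of 6 lay above every Cre-negative mouse (exact two-sided permutation test, p = 0.0022, the smallest this design allows). The list and the division were picked from these same samples, among 36 lists, and this p is not adjusted for that. By camera at the preset correlation the adjusted p was 6.06e-16, and 0.23 with an estimated correlation (0.038 with fry). The difference was 0.46 (0.18 to 0.74) with the mesenteric fat score as a covariate, which argues against fat in the tissue as the whole cause (0 of its 5 tested markers are in another list), and 0.47 (0.17 to 0.76) with Dbp as a covariate, which argues against time of day as far as Dbp measures it. Loss of both alleles stays open for this list, since the interval of heterozygous minus wild type (difference 0.39) was -0.00 to 0.78 and reached 0. Feeding, litter and the Cre transgene were not separated by the design and may contribute as well.

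The 10 splits of 6 samples into 3 and 3 are too few for a share under 0.05. For radiation 10 of the 10 splits gave at least the real 0 genes (highest other 0) and 9 of 10 gave at least the real 4 lists (highest other 13). For Msh2 loss 10 of 10 gave at least 0 genes (highest other 1) and 5 of 10 at least 11 lists (highest other 15). For loss of 1 allele 10 of 10 gave at least 0 genes (highest other 0) and 9 of 10 at least 6 lists (highest other 15). For loss of the second allele 10 of 10 gave at least 0 genes (highest other 0) and 9 of 10 at least 7 lists (highest other 15). The median of the other splits was 7 lists for radiation, 9 for Msh2 loss, 10 for loss of 1 allele and 9 for loss of the second allele. In all 4 comparisons some other split gave more lists than the real one. The number of lists therefore does not set the real groups apart from other splits, and the cause was not tested.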
